A study of Mus musculus with 46 samples.

How the data were processed

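The series holds 46 samples of mouse visceral adipose tissue, of which 20 are RNA-seq libraries and 26 are ChIP-seq samples. Animals of the CORT groups received corticosterone, the main glucocorticoid of rodents, as a model of Cushing's syndrome, and animals of the VEH groups received the vehicle. Per the labels, CORT at 5 weeks stands for active disease and CORT at 15 weeks for the recovered state, each with its own VEH group. RNA was measured in 5 libraries per group. Chromatin immunoprecipitation of 3 histone marks (H3K27ac, H3K4me3 and H3K27me3) was measured in 2 libraries per group, and 2 samples are inputs, the sheared chromatin without immunoprecipitation. Per the labels, the ChIP samples carried a Drosophila chromatin spike-in and the RNA samples did not.

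The gene expression file of the authors gives FPKM values (fragments per kilobase of gene, scaled by library) for 24338 gene symbols in each of the 20 libraries. The submitters' processing notes list TopHat, Bowtie, DESeq2 and DiffBind with the mouse build mm9 and the Drosophila build dm3, with no role per file. The deposited gene tables hold the authors' mean normalized signal per gene, their log2 fold changes with standard errors, and their p-values, raw and adjusted. The deposited ChIP tables hold the log2 of mean normalized reads per site, the log2 difference between groups, and the FDR of the authors' test. Whether the spike-in scaled those values is not stated in the sources used here. Peak lists, 1 for each of 24 ChIP libraries, carry the score of the authors' peak caller, whose lowest value is 50 (the peak names hold MACS). Groups were taken from the labels, and columns were matched to libraries by group and replicate number.

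Depth was read from the FPKM values themselves. Within a gene, the values of a library are whole multiples of a step, and dividing by that step gave whole numbers, taken as reads, for 100% of the 382438 values above 0 (tolerance 0.05). The recovered totals were 25.1 to 42.6 M reads per library (median 30.1 M). The step times the median-ratio size factor of a library was constant (coefficient of variation 0), while the step times the total reads varied by 6.64%. The FPKM therefore carry a median-ratio scaling rather than a scaling by total reads. No depth of the ChIP libraries was read from the peak lists.

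The RNA comparisons used limma 3.58.1 in R 4.3.3, the trend method on log2(FPKM + 1), with 1 model of 4 group means over all 20 libraries. Genes with an FPKM of at least 0.5 in at least 5 libraries were tested (15601 of 22416 with a value above 0). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p below 0.05. The contrasts were CORT minus VEH at 5 weeks, the same at 15 weeks, the difference of these effects (15 weeks minus 5 weeks), and VEH at 15 weeks minus VEH at 5 weeks. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The files name genes by symbol, and symbols were used as given.

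Gene lists were fixed before the data were examined, as were the tests, the filters, the alternatives and the rule for named genes, except where a choice is said to be added later. Of 34 lists, 31 had at least 5 genes tested: glucocorticoid targets, circadian clock, lipogenesis, triglyceride synthesis, lipolysis, fatty acid oxidation, thermogenic genes, oxidative phosphorylation, adipocyte genes, insulin and glucose handling, cholesterol synthesis, extracellular matrix, macrophage, T and NK cell, B and plasma cell, neutrophil and mast cell, inflammation, interferon response, antigen presentation, endothelial, preadipocyte and fibroblast, mesothelial, smooth muscle and pericyte, skeletal muscle, epididymis and testis, lymph node, proliferation, immediate early, ribosomal protein, histone modifiers and endoplasmic reticulum (ER) stress. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 31 lists, and the calls were repeated with an estimated correlation and with fry, which asks only whether the genes of a list move on balance one way. The other 3 lists (pancreas, erythroid and genes of the mitochondrial genome) had fewer than 5 genes tested and were not tested.

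Named genes followed a fixed rule. It takes the 8 largest rises and the 8 largest falls per contrast among called genes with a mean FPKM of at least 1, with no overlap between the groups in the 5 and 15 week contrasts. It adds up to 4 members of each list described, by smallest adjusted p, any measured member of the glucocorticoid or clock lists, and the 10 genes called at both times with the smallest larger adjusted p. Predicted genes and pseudogenes were passed over. Genes outside the rule are said to be so, and some that the rule takes are not reported here. For sites, the 5 gained and the 5 lost with the smallest p per table were taken, and some of these are printed.

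The model was tested on data simulated from the recovered reads, with 16000 of 16199 genes unchanged at 5 weeks. For log2 changes of 0.5, 1 and 2, it recovered 25.4%, 60.6% and 81.8% of changed genes at 5 weeks and 28.4%, 67.7% and 86.2% at 15 weeks. For the difference the shares were 7.69%, 45.2% and 67.7%, and for the vehicle contrast 13.6%, 55.2% and 74.2%. False calls were 5.13%, 3.25%, 7.23% and 2.06% of calls in these contrasts. Such shares may differ where many genes change.

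Peaks were compared with bedtools 2.31.1 (an overlap of at least 1 bp), and tables with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Differential sites were counted from the authors' deposited tables at an FDR below 0.05, since with 2 libraries against 2 an exact permutation test cannot give a p below 0.33. Coordinates are in mm9. No gene annotation of that build was used, so sites carry no gene names.

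The alternatives chosen at the start were a pseudocount of 0.1, no filter, a filter at a mean FPKM of at least 5, quantile normalization, median-ratio rescaling, array weights, fits of only the 2 groups compared, a replicate block, an absolute log2 fold change of at least 1, the authors' deposited table, fry, the estimated correlation, and leaving out each library in turn. For sites they were an FDR below 0.01, an absolute log2 fold of at least 1, autosomes only, a stricter choice of peaks by score, and a reciprocal overlap of 0.5. Added after seeing the data were limma voom on the recovered reads, the same on reads thinned to the smallest library, scaling by total reads, a block with 1 number over both times, site folds centred on the median of their table, and leaving out 7 libraries. These 7 had a testis or epididymis transcript at 50 FPKM or more, or Alb at 500 FPKM or more, and 13 libraries remained. For each RNA count, 100 splits of the same libraries were fitted, the real one included. The files do not say whether each library comes from a separate animal, so the p-values measure the spread between these samples, of which part may be technical. The input-against-mark tables were used only to count sites above input.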

Results

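Visceral fat of mice given corticosterone (CORT) or vehicle (VEH) was profiled at 5 weeks, the time labelled as active Cushing's syndrome, and at 15 weeks, the time labelled as recovered. RNA was measured in 5 libraries in each of the 4 groups, and 3 histone marks were measured in 2 libraries per group. The recovered depth was 37.6 ± 5.16 M reads in CORT and 29.95 ± 3.82 M in VEH at 5 weeks (mean ± SD, n = 5), and 29.01 ± 3.09 M and 30.005 ± 4.33 M at 15 weeks. FPKM values are given as mean ± SD of 5 libraries, and fold changes as log2 of CORT over VEH with their standard error (SE). Simulated changes of log2 1 in few genes were recovered for 60.6% at 5 and 67.7% at 15 weeks, so smaller changes can be missed.

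Adipoq, the adipocyte hormone adiponectin, stood at 1641 to 4016 FPKM in the 20 libraries, and single libraries also carried transcripts of other tissues. Alb, the serum albumin of liver, stood at 2095 FPKM in CORT_5w replicate 2, against 16.8 to 51.8 FPKM in the other libraries of that group. Prm2, a protamine of spermatids, stood at 184 FPKM in CORT_5w replicate 3, at 309 and 129 FPKM in CORT_15w replicates 1 and 5, and at 570.4 FPKM in VEH_15w replicate 5. Crisp1, a secreted protein of the epididymis, stood at 1429.6 FPKM in CORT_5w replicate 4, at 649 FPKM in VEH_5w replicate 3 and at 1261 FPKM in VEH_15w replicate 5. These are 7 libraries: 3 of CORT and 1 of VEH at 5 weeks, and 2 of CORT and 1 of VEH at 15 weeks. Without them the groups hold 2 and 4 libraries at 5 weeks and 3 and 4 at 15 weeks, and many counts below are also given for the remaining 13 libraries. In CORT_15w replicate 4, transcripts of B and plasma cells were high (Igj at 109 FPKM, Cd79b at 12.8 FPKM), as was the chemokine Cxcl13 (71.1 FPKM). Pearson correlations between libraries ran from 0.863 to 0.989, and the lowest within a group was 0.909.

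**Figure D1:**
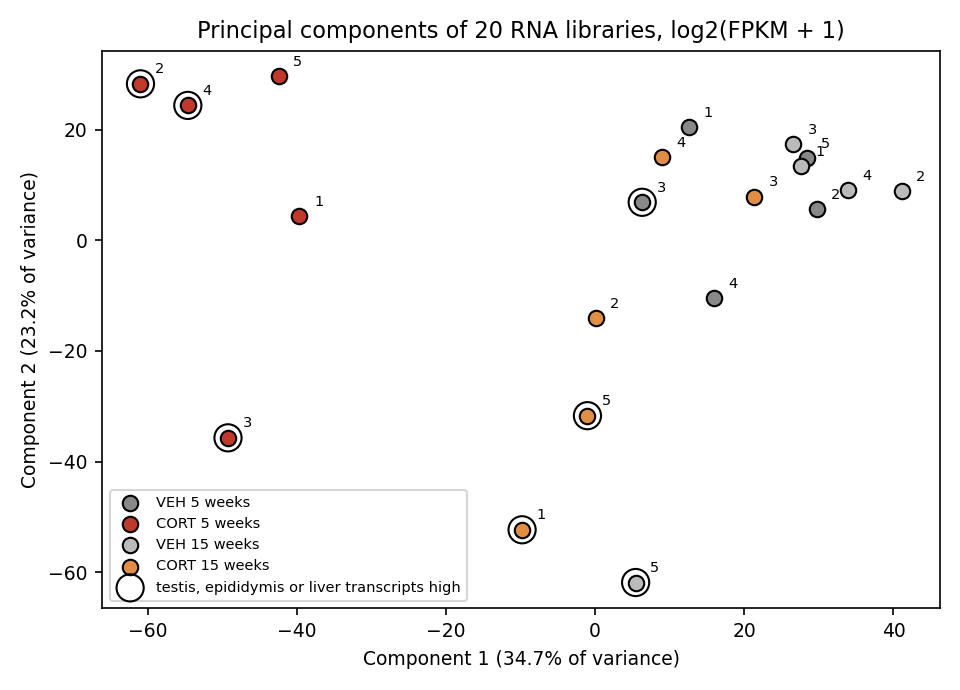
The 20 RNA libraries on the first and second principal components of log2(FPKM + 1), which carry 34.7% and 23.2% of the variance; points are libraries, colours are the 4 groups, and circles mark the 7 libraries with testis, epididymis or liver transcripts. The 5 CORT libraries of 5 weeks lie apart from the other groups on the first axis, and the 4 libraries lowest on the second axis carry spermatid transcripts.

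The comparison at 5 weeks asked how the fat tissue differed during active disease. Lep, the gene of the satiety hormone leptin, rose from 49.8 ± 54.5 FPKM in VEH to 676 ± 169.7 FPKM in CORT (log2 fold change 4.36, SE 0.66, adjusted p = 4.46e-05). Cfd, which encodes the adipocyte protease adipsin, fell from 9248 ± 2257 to 495 ± 201 FPKM (log2 fold change -4.27, SE 0.30, adjusted p = 1.36e-08). Timp1, an inhibitor of matrix metalloproteases, rose from 1.88 ± 0.727 to 42.7 ± 19.4 FPKM (log2 fold change 3.80, SE 0.39, adjusted p = 8.24e-07), and Spp1, which encodes the matrix protein osteopontin, rose from 2.73 ± 2.24 to 39.04 ± 22.9 FPKM. Among the largest rises were also Hspb7, a small heat shock protein (log2 fold change 4.04, SE 0.37), and Atp6v0d2, a proton pump subunit (3.65, SE 0.55). They included Mmp12, the macrophage elastase (3.63, SE 0.63), Rgs1, a G protein regulator (3.51, SE 0.50), and Slc5a7, the choline transporter (3.51, SE 0.20). The largest falls after Cfd were those of the transcription factor Irf4 (-3.65, SE 0.56), the acyl-CoA synthetase Acsm3 (-2.99, SE 0.30) and Fam13a (-2.90, SE 0.27). Next came the imprinted gene Zim1 (-2.85, SE 0.29), the methyltransferase Inmt (-2.81, SE 0.29), the signalling inhibitor Cish (-2.48, SE 0.44) and the MYC family member Mycl (-2.44, SE 0.31). These 16 were taken among genes with no overlap between the CORT and VEH libraries.

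In all, 3485 genes rose and 3350 fell in CORT at 5 weeks, 43.8% of the 15601 tested. Of these, 627 rose and 380 fell at least 2-fold. The 10 libraries of the 2 groups did not overlap in 4516 genes (28.9%), against 0.794% by chance, and 4327 of these genes were called. In the 13 libraries left without the 7, 2434 genes rose and 1963 fell. Rises were 51.0% of the calls as deposited, 45.2% after scaling by total reads and 45.3% after quantile normalization. The authors' deposited table calls 3936 genes up and 3606 down, and 6524 of the 6835 genes called here are called there, 0 of them in the opposite direction.

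Many genes of lipid making rose. All 16 called members of the cholesterol synthesis list rose, of 19 tested (15 without the 7 libraries). They included lanosterol synthase Lss (8.03 ± 1.31 FPKM in CORT and 2.49 ± 0.257 FPKM in VEH) and the sterol dehydrogenase Nsdhl (22.5 ± 3.92 FPKM in CORT and 6.62 ± 0.775 FPKM in VEH). Cholesterol synthesis passed camera at adjusted p = 4.44e-10, against adjusted p = 0.0753 with an estimated correlation. Of 21 lipogenesis genes 13 rose and 2 fell (13 and 2 without the 7 libraries). Rises included Acly, which makes the acetyl-CoA of fatty acid synthesis (157 ± 32.2 FPKM in CORT and 34.7 ± 3.47 FPKM in VEH, log2 fold change 2.12, SE 0.11, adjusted p = 1.15e-09), and the acetyl-CoA synthetase Acss2 (59.8 ± 14.01 FPKM in CORT and 14.6 ± 2.18 FPKM in VEH). Lipogenesis passed camera at adjusted p = 8.77e-05, against adjusted p = 0.4005 with an estimated correlation. The list of triglyceride synthesis was not called (adjusted p = 0.236 by camera), with 7 genes up and 5 down of 20 (7 and 3 without the 7 libraries). On it, Dgat2, the last step of triglyceride making, rose from 52.3 ± 5.36 to 479.7 ± 113 FPKM (log2 fold change 3.15, SE 0.20, adjusted p = 3.55e-09), and Agpat2, an earlier step, had a log2 fold change of 1.71, SE 0.18. The glucose carrier Slc2a4 rose as well (1.21, SE 0.16), while Pnpla2, the lipase that starts triglyceride breakdown, fell (-1.18, SE 0.17).

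Of 19 fatty acid oxidation genes 9 rose and 1 fell, among them Cpt1a, the carrier step into mitochondria (42.9 ± 7.25 FPKM in CORT and 24.4 ± 3.25 FPKM in VEH), and the dehydrogenase Acadm (0.83, SE 0.14). The list passed with adjusted p = 0.0324 by camera and adjusted p = 0.745 with an estimated correlation. Of 30 oxidative phosphorylation genes 10 rose and 1 fell, among them cytochrome c, Cycs (99.4 ± 12.2 FPKM in CORT and 45.1 ± 12.7 FPKM in VEH), and the succinate dehydrogenase subunit Sdhc (0.58, SE 0.11). Oxidative phosphorylation passed camera at adjusted p = 0.00743, against adjusted p = 0.764 with an estimated correlation. Without the 7 libraries, 3 genes of fatty acid oxidation rose and 1 fell, 2 of oxidative phosphorylation rose and 0 fell, and neither list passed (adjusted p = 0.366 for each).

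Markers of macrophages, matrix and dividing cells rose. Of 23 macrophage genes 15 rose and 3 fell (13 and 1 without the 7 libraries). The macrophage list passed camera at adjusted p = 0.00588, against adjusted p = 0.745 with an estimated correlation. Trem2, a receptor of lipid-laden macrophages, was 42.1 ± 20.5 FPKM in CORT and 5.596 ± 2.39 FPKM in VEH, and the lysosomal marker Cd68 was 127 ± 54.5 FPKM in CORT and 33.7 ± 10.7 FPKM in VEH. Ccr2, the chemokine receptor of recruited monocytes, fell (-1.76, SE 0.32). Of 30 extracellular matrix genes 13 rose and 3 fell (15 and 3 without the 7 libraries). Rises included Sparc (1649 ± 327 FPKM in CORT and 628 ± 50.1 FPKM in VEH) and the collagen gene Col6a1 (1.59, SE 0.20). The matrix list passed camera at adjusted p = 0.00588, against adjusted p = 0.732 with an estimated correlation. Of 24 proliferation genes 18 rose and 1 fell (19 and 0 without the 7 libraries). Among the rises were cyclin E1, Ccne1 (2.73 ± 0.6399 FPKM in CORT and 0.399 ± 0.116 FPKM in VEH), and the replication helicase subunit Mcm5 (1.28, SE 0.18). The proliferation list passed camera at adjusted p = 8.12e-07, against adjusted p = 0.454 with an estimated correlation. Of 19 immediate early and heat shock genes 11 rose and 0 fell (8 and 0 without the 7 libraries). Rises here included the chaperone Hspb1 (198 ± 50.7 FPKM in CORT and 40.3 ± 6.43 FPKM in VEH) and the transcription factor Egr2 (1.67, SE 0.23). The immediate early list passed camera at adjusted p = 0.00201, against adjusted p = 0.732 with an estimated correlation. Of 22 genes of ER stress 14 rose and 5 fell (9 and 2 without the 7 libraries). The ER stress list passed camera at adjusted p = 0.0251, against adjusted p = 0.732 with an estimated correlation. On this list, Ddit3 (0.98, SE 0.11) and Calr (0.91, SE 0.16) rose, and Chac1, which degrades glutathione, fell (-1.47, SE 0.25). The inflammation list held 10 rises and 7 falls of 28 (10 and 4 without the 7 libraries) and was not called (adjusted p = 0.653 by camera). On it, the chemokine Ccl2 rose (64.2 ± 33.3 FPKM in CORT and 7.85 ± 2.71 FPKM in VEH, log2 fold change 2.73, SE 0.33, adjusted p = 4.77e-06), and the eosinophil chemokine Ccl11 fell (-1.39, SE 0.19).

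Genes of antigen presentation, of T and NK cells and of vessels fell. Of 14 antigen presentation genes 11 fell and 1 rose (9 and 1 without the 7 libraries). Falls included the class II gene H2-Eb1 (30.02 ± 8.67 FPKM in CORT and 113 ± 17.999 FPKM in VEH, log2 fold change -1.91, SE 0.17, adjusted p = 2.22e-07) and Cd74, the class II chaperone (124 ± 33.9 FPKM in CORT and 345 ± 55.1 FPKM in VEH). Antigen presentation passed camera at adjusted p = 8.77e-05, against adjusted p = 0.561 with an estimated correlation. Of 14 T and NK cell genes 10 fell and 1 rose (6 and 1 without the 7 libraries), among them Cd2 (-0.999, SE 0.16). The lymphocyte list passed camera at adjusted p = 0.000733, against adjusted p = 0.4005 with an estimated correlation. Of 22 endothelial genes 17 fell and 2 rose (14 and 2 without the 7 libraries). The angiopoietin receptor Tek (6.84 ± 1.92 FPKM in CORT and 17.5 ± 2.53 FPKM in VEH) and the junction protein Pecam1 (-1.28, SE 0.17) were among the falls. The endothelial list passed camera at adjusted p = 2.34e-06, against adjusted p = 0.454 with an estimated correlation. Of 25 interferon response genes 12 fell and 0 rose (6 and 0 without the 7 libraries), among them Usp18 (-0.68, SE 0.14). The interferon list passed camera at adjusted p = 0.00377, against adjusted p = 0.732 with an estimated correlation. Of 30 histone modifiers 20 fell and 1 rose (7 and 0 without the 7 libraries). Among the falls were Suz12, a subunit of the complex that writes H3K27me3 (12.5 ± 0.285 FPKM in CORT and 21.03 ± 2.39 FPKM in VEH), and the H3K4 methyltransferase Kmt2c (-0.58, SE 0.087). The histone modifier list passed camera at adjusted p = 7.09e-05, against adjusted p = 0.343 with an estimated correlation. Of 11 neutrophil and mast cell genes 6 fell and 1 rose (6 and 0 without the 7 libraries), among them the protease Elane (-1.53, SE 0.17). The neutrophil list passed camera at adjusted p = 0.0424, against adjusted p = 0.732 with an estimated correlation.

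Known targets of the glucocorticoid receptor fell more often than they rose in the animals given the glucocorticoid. Of 30 such genes 15 fell and 5 rose (12 and 5 without the 7 libraries). The glucocorticoid list passed camera at adjusted p = 0.0211, against adjusted p = 0.732 with an estimated correlation, and adjusted p = 0.0571 without the 7 libraries. The clock and receptor target Per1 was 5.92 ± 2.24 FPKM in CORT and 19.1 ± 4.03 FPKM in VEH (log2 fold change -1.57, SE 0.22, adjusted p = 2.27e-05). The kinase Sgk1 was 10.99 ± 3.702 FPKM in CORT and 31.3 ± 7.47 FPKM in VEH (-1.45, SE 0.23), and the transcription factor Klf9 fell too (-0.99, SE 0.14). The receptor itself, Nr3c1, fell (-0.52, SE 0.14), and Hsd11b1, which makes active glucocorticoid within cells, rose (295 ± 77.6 FPKM in CORT and 114 ± 37.3 FPKM in VEH, log2 fold change 1.39, SE 0.27, adjusted p = 0.000451). The metallothionein Mt2 rose (587 ± 131 FPKM in CORT and 152 ± 77.4 FPKM in VEH). Fkbp5 (log2 fold change -0.06, SE 0.24, adjusted p = 0.864) and Tsc22d3 (log2 fold change 0.28, SE 0.28, adjusted p = 0.451), both classic targets, did not pass the test. Both were named after their values were seen, outside the rule. On the clock list, which was not called (adjusted p = 0.275 by camera), Npas2 fell (-1.29, SE 0.26) and Bhlhe41 rose (0.71, SE 0.15). It held 3 rises and 7 falls of 19 (3 and 3 without the 7 libraries). Of 25 genes of insulin and glucose handling 13 fell and 5 rose (7 and 5 without the 7 libraries), among them the insulin receptor Insr (26.6 ± 3.15 FPKM in CORT and 61.9 ± 14.2 FPKM in VEH, log2 fold change -1.17, SE 0.15, adjusted p = 9.81e-06). The insulin list passed camera at adjusted p = 0.0251, against adjusted p = 0.732 with an estimated correlation, and adjusted p = 0.1001 without the 7 libraries.

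**Figure D2:**
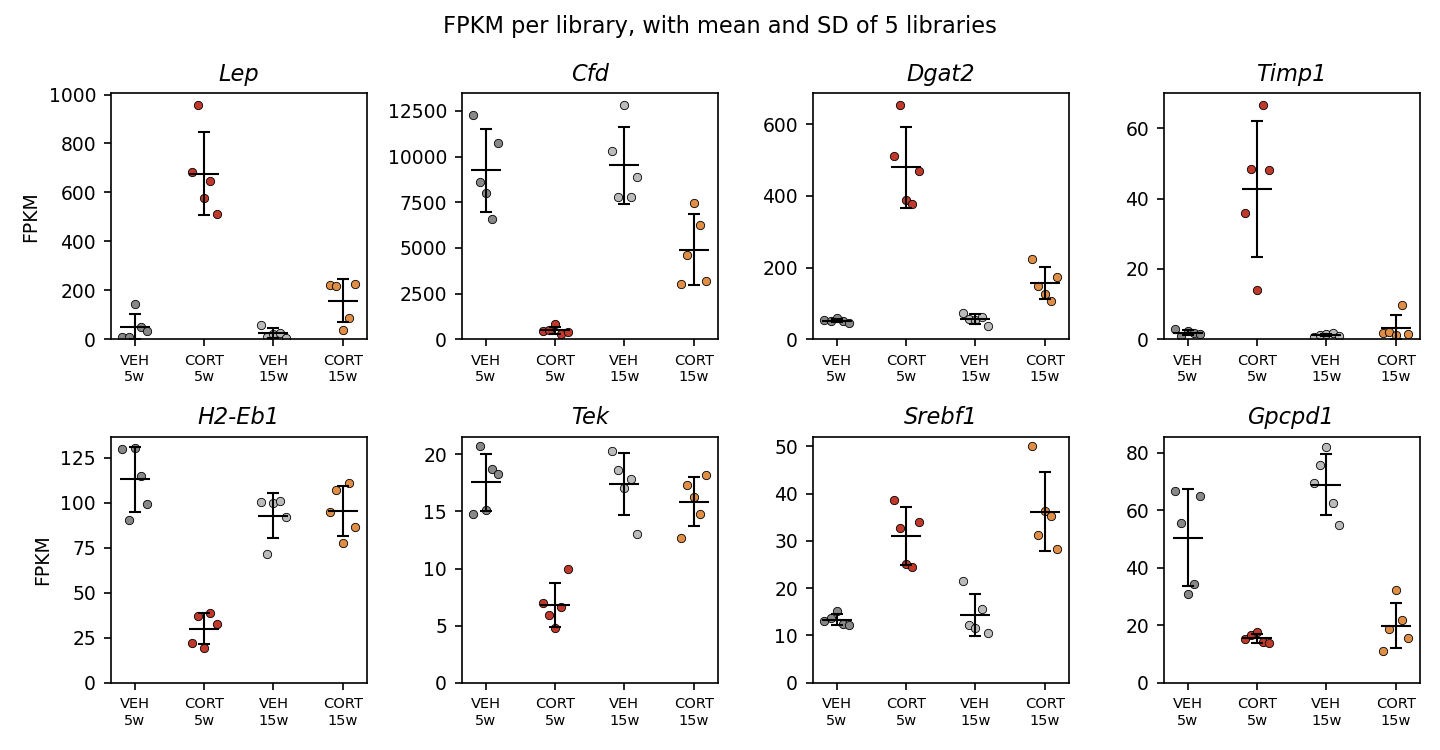
FPKM on a linear axis of 8 genes in each of the 20 libraries, with the mean ± SD of the 5 libraries of each group. Lep averages 158 ± 88.9 FPKM in CORT and 24.1 ± 19.9 in VEH at 15 weeks.

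The other lists were not called at 5 weeks. They were lipolysis (5 up, 6 down of 16, adjusted p = 0.424), thermogenic genes (1 and 2 of 10, 0.622) and adipocyte genes (3 and 4 of 18, 0.999). B and plasma cells (0 and 1 of 8, 0.265), preadipocytes and fibroblasts (2 and 4 of 18, 0.201) and mesothelial genes (0 and 0 of 12, 0.898) did not pass. Neither did smooth muscle and pericytes (3 and 4 of 13, 0.742) or skeletal muscle (2 and 1 of 6, 0.588). The last were epididymis and testis (0 and 1 of 8, 0.898), lymph node (1 and 2 of 7, 0.622) and ribosomal proteins (0 and 0 of 30, 0.724). Median and mean differed in sign for the mesothelial list (-0.04 and 0.05), and the smooth muscle list had a median of 0.13, a mean of 0.01 and a test pointing down. Adjusted over the list alone, all counts of members were equal to those over all genes except for oxidative phosphorylation (10 up, 0 down), insulin handling (5 and 14), extracellular matrix (14 and 3), and B and plasma cells (0 and 0). They also differed for interferon response (0 and 13), endothelial (3 and 17), epididymis and testis (0 and 0), proliferation (21 and 1) and histone modifiers (2 and 20).

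Of 31 lists, camera with the preset correlation called 17 at 5 weeks (13 without the 7 libraries), and fry called 18. With an estimated correlation camera called 0 lists (3 at an unadjusted p below 0.05), and for every called list of the 3 contrasts this gave the highest adjusted p of all its alternatives. Fry also called the clock list (adjusted p = 0.0224) and triglyceride synthesis (0.00675) and did not call oxidative phosphorylation (0.0808). Leaving out single libraries ended 4 list calls. ER stress was not called without CORT_5w replicate 5 (adjusted p = 0.0550) or VEH_5w replicate 4 (0.0842) (range 0.0102 to 0.732 over its alternatives). Fatty acid oxidation was not called without replicate 2 or 3 of CORT_5w or 3 or 4 of VEH_5w (0.0590 to 0.0953), range 0.01199 to 0.745. Neutrophil and mast cells were not called without CORT_5w replicate 1 or 2 or VEH_5w replicate 1 (0.0554 to 0.146), range 0.00358 to 0.732, and oxidative phosphorylation not without VEH_5w replicate 4 (0.0731), range 0.000180 to 0.764. Quantile normalization ended the same 4 calls (adjusted p = 0.166, 0.34033, 0.134 and 0.610254 in this order) and called ribosomal proteins (0.00113). Voom (0.0684), thinned reads (0.0715) and scaling by total reads (0.0786) ended the neutrophil call.

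**Figure D3:**
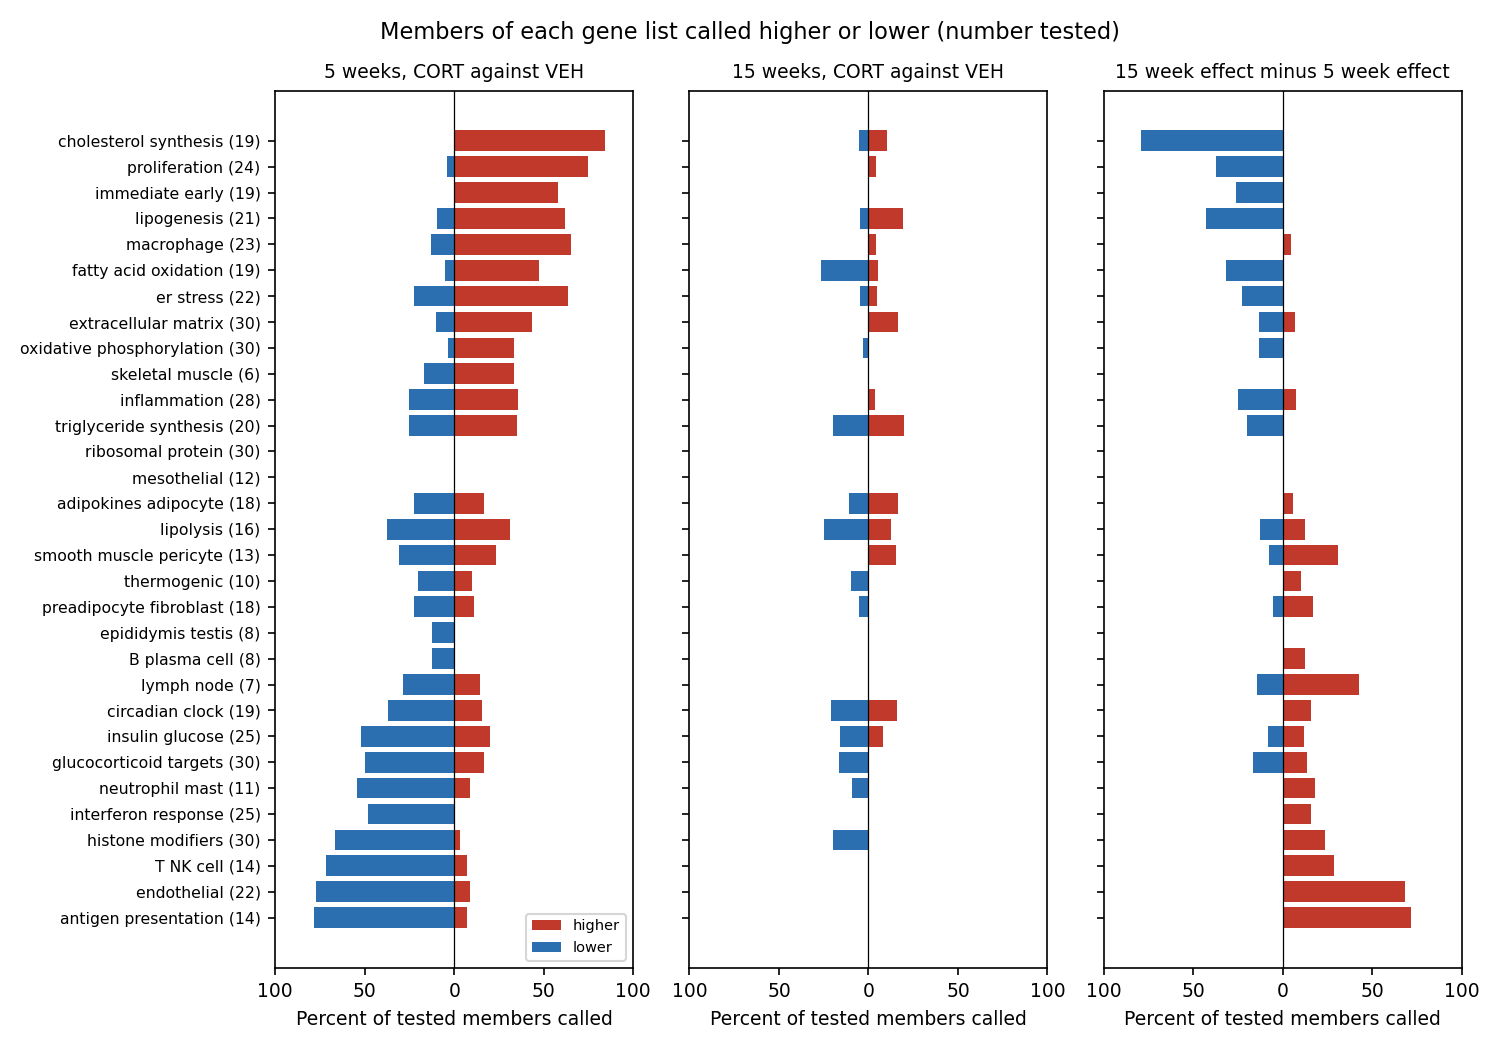
Percent of the tested members of each gene list called higher or lower (adjusted p below 0.05), for the effect at 5 weeks, at 15 weeks and their difference, with the number tested in brackets. The highest shares at 5 weeks are 16 of 19 higher for cholesterol synthesis and 11 of 14 lower for antigen presentation, and at 15 weeks 4 of 20 higher for triglyceride synthesis and 5 of 19 lower for fatty acid oxidation.

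The comparison at 15 weeks asked what differed once the disease is labelled as recovered. Lep was 158 ± 88.9 FPKM in CORT and 24.1 ± 19.9 FPKM in VEH (log2 fold change 2.74, SE 0.66, adjusted p = 0.0143), and without the 7 libraries it was not called (adjusted p = 0.181). The largest rises with no overlap between the groups were those of Klhdc7a (1.90, SE 0.32), Fam20c, the kinase of secreted proteins (15.7 ± 5.18 FPKM in CORT and 3.98 ± 1.85 FPKM in VEH, log2 fold change 1.77, SE 0.22, adjusted p = 0.000608), and the matrix proteoglycan Prelp (1.69, SE 0.30). The next were the lactate receptor Hcar1 (1.69, SE 0.33), Fgf13 (1.66, SE 0.31), Slc5a7 (1.61, SE 0.20), Gpd1, which makes the glycerol phosphate of triglycerides (135 ± 37.8 FPKM in CORT and 43.3 ± 10.5 FPKM in VEH), and Hspb7 (1.57, SE 0.37). The largest falls were those of the apolipoprotein Apoc3 (1.83 ± 0.831 FPKM in CORT and 24.7 ± 16.4 FPKM in VEH, log2 fold change -3.01, SE 0.74, adjusted p = 0.0157) and the peroxisomal enzymes Ehhadh (-1.92, SE 0.44) and Acot3 (-1.57, SE 0.36). Falls also included the choline phospholipid enzyme Gpcpd1 (19.9 ± 7.96 FPKM in CORT and 68.9 ± 10.6 FPKM in VEH), the ubiquitin ligase Rnf125 (-1.74, SE 0.27), the cAMP phosphodiesterase Pde4d (-1.66, SE 0.27), the mitochondrial carrier Slc25a25 (-1.66, SE 0.25) and the symbol Mir1904 (-1.60, SE 0.39).

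In all, 598 genes rose and 1061 fell in CORT at 15 weeks, 10.6% of those tested, with 76 rising and 76 falling at least 2-fold. The groups did not overlap in 1259 genes (8.07%), against 0.794% by chance, and 985 of these were called. The 13 libraries left without the 7 gave 55 rises and 94 falls. Single libraries moved these counts by more than 1.5 times. Without CORT_15w replicate 1, 260 genes rose and 438 fell, without VEH_15w replicate 2, 356 rose and 661 fell, and without VEH_15w replicate 3, 375 rose and 557 fell. Fitted without the 5 week groups, 340 rose and 568 fell. Rises were 36.0% of the calls as deposited, 43.3% after quantile normalization (744 up, 975 down) and 63.4% after scaling by total reads (1083 up, 626 down), so the balance of rises and falls depends on the scaling. The authors' deposited table calls 985 genes up and 1228 down, and it shares 1513 of the 1659 calls, 0 of them in the opposite direction.

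Genes of triglyceride and fatty acid making were among the calls, although neither list passed (adjusted p = 0.885 and 0.256 by camera). Of 20 triglyceride genes 4 rose and 4 fell (2 and 0 without the 7 libraries), among them Dgat2 (156 ± 44.6 FPKM in CORT and 56.4 ± 13.6 FPKM in VEH, log2 fold change 1.44, SE 0.20, adjusted p = 0.000608) and the acyltransferase Gpam (-1.25, SE 0.23). Of 21 lipogenesis genes 4 rose and 1 fell (1 and 0 without the 7 libraries), among them their transcription factor Srebf1 (36.2 ± 8.35 FPKM in CORT and 14.3 ± 4.48 FPKM in VEH, log2 fold change 1.30, SE 0.17, adjusted p = 0.000608) and Pnpla3 (1.42, SE 0.26). Of 19 cholesterol genes 2 rose and 1 fell (0 and 0 without the 7 libraries), Mvk among the rises (0.50, SE 0.11), and the list passed with adjusted p = 0.03002 by camera and adjusted p = 0.965 with an estimated correlation. Slc2a4 (0.68, SE 0.16) and Cpt1a (0.57, SE 0.12) rose. On the list of insulin handling, not called (2 up, 4 down of 25, adjusted p = 0.158), the receptor adaptors Grb14 and Grb10 went up (1.15, SE 0.24) and down (-0.81, SE 0.19).

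Of 30 extracellular matrix genes 5 rose and 0 fell (0 and 0 without the 7 libraries). Among these rises were Col15a1 (59.6 ± 29.1 FPKM in CORT and 19.7 ± 7.77 FPKM in VEH) and Mmp12 (35.05 ± 34.1 FPKM in CORT and 2.12 ± 1.48 FPKM in VEH, log2 fold change 2.88, SE 0.63, adjusted p = 0.00943). The matrix list passed camera at adjusted p = 0.00334, against adjusted p = 0.965 with an estimated correlation. Of 30 glucocorticoid targets 5 fell and 0 rose (0 and 0 without the 7 libraries), among them the cell cycle inhibitor Cdkn1a (10.8 ± 1.84 FPKM in CORT and 22.3 ± 5.84 FPKM in VEH) and the kinase Map3k6 (-0.67, SE 0.16). The glucocorticoid list passed camera at adjusted p = 0.00482, against adjusted p = 0.965 with an estimated correlation. On the clock list (3 up, 4 down of 19, adjusted p = 0.885), the clock activator Arntl (-0.92, SE 0.22) and the repressor Cry1 (-0.75, SE 0.18) fell and Bhlhe41 rose (0.79, SE 0.15). Of 30 oxidative phosphorylation genes 1 fell, and the list passed with adjusted p = 0.0132 by camera and adjusted p = 0.965 with an estimated correlation. The list of B and plasma cells (0 called of 8, median 0.49, adjusted p = 0.0257 by camera and adjusted p = 0.965 with an estimated correlation) pointed up. So did that of the lymph node (0 of 7, median 0.36, adjusted p = 0.03002 by camera and adjusted p = 0.965 with an estimated correlation). Single genes of lists that did not pass included the integrin Itgax (1.69, SE 0.40), the inhibitor of inflammation Tnfaip3 (0.66, SE 0.13), Elane (-0.74, SE 0.17), the histone modifiers Suz12 (-0.52, SE 0.10) and Sirt1 (-0.54, SE 0.11), and asparagine synthetase, Asns (-1.12, SE 0.23).

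The other lists were not called at 15 weeks. They were lipolysis (2 up, 4 down, adjusted p = 0.938), fatty acid oxidation (1 and 5, 0.158), thermogenic (0 and 1, 0.885), and adipocyte (3 and 2, 0.885). Of the cell type and immune lists they were macrophage (1 and 0, 0.158), T and NK cell (0 and 0, 0.885), neutrophil and mast cell (0 and 1, 0.179), inflammation (1 and 0, 0.2701), interferon response (0 and 0, 0.579), and antigen presentation (0 and 0, 0.158). Others were endothelial (0 and 0, 0.661), preadipocyte and fibroblast (0 and 1, 0.885), mesothelial (0 and 0, 0.141), smooth muscle (2 and 0, 0.1102), and skeletal muscle (0 and 0, 0.533). The rest were epididymis and testis (0 and 0, 0.885), proliferation (1 and 0, 0.1102), immediate early (0 and 0, 0.885), ribosomal protein (0 and 0, 0.104), histone modifiers (0 and 6, 0.0755) and ER stress (1 and 1, 0.938). Adjusted over the list alone, members up and down were 1 and 7 for glucocorticoid targets, 4 and 6 for clock, 4 and 2 for lipogenesis, 4 and 6 for triglyceride synthesis, 4 and 5 for lipolysis, 1 and 7 for fatty acid oxidation, 0 and 0 for thermogenic and 4 and 4 for adipocyte. They were 4 and 9 for insulin handling, 0 and 2 for neutrophil and mast cell, 3 and 0 for smooth muscle, 2 and 0 for skeletal muscle, 0 and 0 for proliferation, 0 and 8 for histone modifiers and 3 and 4 for ER stress, and equal for the other lists. Median, mean and test differed in sign for clock (median 0.18, mean below 0, test up), lipolysis (both above 0, test down), thermogenic (-0.02, 0.06, up), adipocyte (-0.20, 0.06, down), skeletal muscle (-0.01, 0.26, up) and ER stress (both below 0, test up).

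At 15 weeks camera called 6 lists with the preset correlation and 0 with an estimated one (0 at an unadjusted p below 0.05), and fry called 0 (4 at an unadjusted p below 0.05). Without the 7 libraries camera called 14, among them the newly called lists of macrophages (adjusted p = 0.00319), proliferation (0.00376), smooth muscle (0.0112), insulin handling (0.0125), histone modifiers (0.0125), inflammation (0.0181), antigen presentation (0.0474) and endothelial genes (0.0474). The calls that single libraries ended, with adjusted p without the library, were B and plasma cells (CORT_15w replicate 4, high in Igj, 0.211, VEH_15w replicates 4 and 5, 0.0552 and 0.0562) and lymph node (same libraries, 0.0562 to 0.323). They were also cholesterol synthesis (CORT_15w replicates 1 and 5, VEH_15w replicates 2 and 4, 0.0602 to 0.0776) and oxidative phosphorylation (CORT_15w replicate 4 0.0681, VEH_15w replicate 3 0.156). Lists called only with a library left out were histone modifiers (CORT_15w replicate 3, VEH_15w replicates 3 and 5, 0.0185 to 0.0353), insulin handling (VEH_15w replicate 5 0.0246), and macrophage (CORT_15w replicate 5 0.0261). So were mesothelial (VEH_15w replicate 1 0.00864), proliferation (CORT_15w replicate 2 0.0151, VEH_15w replicate 5 0.000837) and ribosomal protein (replicates 2 and 4 of both groups, 0.00796 to 0.0422). Over their alternatives the adjusted p ran from 0.00146 to 0.965 for B and plasma cells, 0.00569 to 0.965 for the lymph node, 0.00965 to 0.965 for cholesterol synthesis, 0.00124 to 0.965 for oxidative phosphorylation, 0.000446 to 0.965 for glucocorticoid targets and 3.49e-05 to 0.965 for extracellular matrix. Quantile normalization ended glucocorticoid targets (0.0861), cholesterol synthesis (0.0861), oxidative phosphorylation (0.534), B and plasma cells (0.122) and lymph node (0.135). Fry ended all 6, from 0.210396 (glucocorticoid targets) to 0.511 (oxidative phosphorylation). Scaling by total reads ended B and plasma cells and lymph node (0.1004 each), and voom and thinned reads ended cholesterol synthesis (0.0540 and 0.0580) and lymph node (0.0525 and 0.0580). A pseudocount of 0.1 ended lymph node (0.0582).

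Of the 46 calls of named genes at 15 weeks, 19 held without the 7 libraries. The 27 that did not were Acot3, Arntl, Asns, Bhlhe41, Cdkn1a, Col15a1, Cpt1a, Cry1, Ehhadh, Elane, Fgf13, Gpam, Grb14, Hcar1, Hspb7, Itgax, Klhdc7a, Lep, Map3k6, Mir1904, Mmp12, Mvk, Pnpla3, Prelp, Sirt1, Slc2a4 and Suz12, with adjusted p from 0.0520 (Mmp12) to 0.183 (Mir1904). All 27 kept their sign with 3 and 4 libraries, 8 had a fold at least as large (Arntl -1.04, SE 0.27; Cdkn1a -1.07, SE 0.24), and the median ratio to the fold of all libraries was 0.801 and that of the SE 1.12. Mir1904 was also not called without CORT_15w replicate 1 (adjusted p = 0.0540) or in the authors' deposited table. Apoc3 was not called by limma voom on the recovered reads (adjusted p = 0.0660) or on thinned reads (0.0510), and Grb10 not in a fit of only the 2 groups compared (adjusted p = 0.0502).

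A part of the changes of 5 weeks was present at 15 weeks. Dgat2 was the triglyceride enzyme with the clearest call at both times, with log2 fold changes of 3.15 and 1.44. Fam20c rose at both times (2.65 and 1.77), as did the matrix protein gene Crtac1 (1.57 and 1.52), the retinal reductase Dhrs3 (1.06 and 1.05), the ephrin receptor Ephb2 (1.01 and 0.87), the prostaglandin receptor Ptger3 (1.89 and 1.29), Rtn4rl1 (1.23 and 1.18) and Slc35c2 (0.61 and 0.49). Gpcpd1 fell at both (-1.59 and -1.81), as did the signalling adaptor Gab2 (-0.59 and -0.74). Of 598 rises at 15 weeks, 427 were also rises at 5 weeks (71.4%), where independent lists would share 134 (odds ratio 9.75). Of 1061 falls, 649 were also falls at 5 weeks (61.2%), where 228 would be shared (odds ratio 6.90). Genes are not independent, so these ratios overstate the evidence, and the contrasts share no library. Other splits of the 15 week libraries, with 5 week calls kept, shared up to 781 genes. Of the 1120 genes called at both times 1076 went in the same direction and 44 in opposite directions, and 539 genes were called at 15 weeks and not at 5 weeks. Among genes called at 5 weeks the median ratio of the effects was 0.242, and across all tested genes the effects correlated at r = 0.517. The genes called in the same direction at both times numbered 123 without the 7 libraries. They numbered 538 without CORT_15w replicate 1, 694 and 704 without VEH_15w replicates 2 and 3, and 610 in fits of 2 groups.

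**Figure D4:**
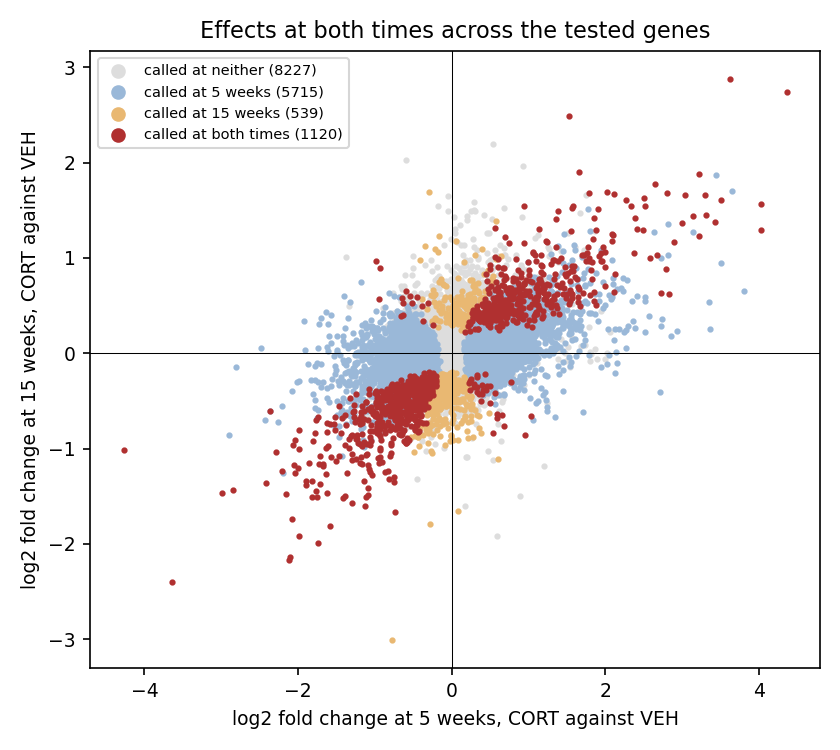
Log2 fold change of CORT over VEH at 5 weeks (horizontal axis) and at 15 weeks (vertical axis) of each of the 15601 tested genes, coloured by the time at which it was called. Of the 1120 genes called at both times 1076 have the same sign at both.

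The difference of the effects asked which changes of 5 weeks were smaller, or larger, at 15 weeks. Cfd had the largest rise of effect, with 4913 ± 1932 FPKM in CORT and 9522 ± 2114 in VEH at 15 weeks, a difference of 3.25, SE 0.42 (adjusted p = 0.000159). Timp1 had the largest drop, with 3.24 ± 3.603 and 1.23 ± 0.375 FPKM at 15 weeks, a difference of -3.15, SE 0.55 (adjusted p = 0.00138). Effects also rose for Inmt (2.66, SE 0.41), Cish (2.53, SE 0.63), the opioid precursor Penk (2.27, SE 0.29), complement C7 (2.07, SE 0.58), Fcrls (2.07, SE 0.26), the collagen gene Col6a5 (2.04, SE 0.61) and Fam13a (2.04, SE 0.39). They dropped for Chil3, a chitinase-like protein of macrophages (-3.13, SE 0.49), Rnase2a (-3.11, SE 0.39), the interleukin 1 receptor antagonist Il1rn (-2.81, SE 0.40), Rgs1 (-2.56, SE 0.71), Hspb7 (-2.46, SE 0.52), Ccl2 (-2.44, SE 0.47) and the fatty acid binding protein Fabp5 (-2.38, SE 0.24). In all, 1025 genes had a higher and 1575 a lower effect at 15 weeks (16.7% of those tested), 223 and 247 of them by at least 2-fold. Of the genes called at 5 weeks, 2347 had a called difference towards 0 and 0 away from 0, a count that shares the 5 week values with the call. Without the 7 libraries 214 were higher and 502 lower, without VEH_5w replicate 2 652 were higher, and without VEH_15w replicate 3 664 were higher. Higher effects were 39.4% of calls as deposited, 49.7% after quantile normalization (1027 and 1041) and 65.5% after scaling by total reads (1782 and 938), which moves the median of all genes from -0.02 to 0.11.

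Effects dropped for the lists of lipid making. Of 19 cholesterol genes 15 dropped and 0 rose in effect (12 and 0 without the 7 libraries), Lss (-1.13, SE 0.15) and Nsdhl (-1.30, SE 0.18) among them. Cholesterol synthesis passed camera at adjusted p = 5.59e-10, against adjusted p = 0.0782 with an estimated correlation. Of 21 lipogenesis genes 9 dropped (10 without the 7 libraries), Acly (-1.87, SE 0.16) and Acss2 (-2.09, SE 0.19) among them. Lipogenesis passed camera at adjusted p = 4.26e-05, against adjusted p = 0.3796 with an estimated correlation. Of 20 triglyceride genes 4 dropped (3 without the 7 libraries), Dgat2 among them (-1.71, SE 0.28). Triglyceride synthesis passed camera at adjusted p = 0.0356, against adjusted p = 0.595 with an estimated correlation. Oxidative phosphorylation (0 up, 4 down of 30, Cycs at -1.53, SE 0.25, adjusted p = 4.52e-06 by camera and adjusted p = 0.574 with an estimated correlation) dropped as a list. So did fatty acid oxidation (0 and 6 of 19, Hadhb at -0.92, SE 0.19, adjusted p = 0.000497 by camera and adjusted p = 0.574 with an estimated correlation). Both had 0 called genes without the 7 libraries. Proliferation (0 and 9 of 24, adjusted p = 6.56e-06 by camera and adjusted p = 0.5004 with an estimated correlation) included Ccne1 (-1.19, SE 0.22) and Pcna (-1.03, SE 0.23). Immediate early genes (0 and 5 of 19, adjusted p = 0.000993 by camera and adjusted p = 0.574 with an estimated correlation) included Hspb1 (-2.03, SE 0.23). ER stress held 0 and 5 of 22 (adjusted p = 0.0127 by camera and adjusted p = 0.595 with an estimated correlation). These 3 lists had 3, 3 and 1 called drops without the 7 libraries.

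Effects rose for genes of antigen presentation and vessels. Of 14 antigen presentation genes 10 rose (8 without the 7 libraries), among them H2-Eb1 (1.95, SE 0.24) and Cd74 (1.68, SE 0.25). Antigen presentation passed camera at adjusted p = 1.89e-07, against adjusted p = 0.3796 with an estimated correlation. Of 22 endothelial genes 15 rose (2 without the 7 libraries), among them Tek (1.14, SE 0.21) and Tie1 (1.30, SE 0.25). The endothelial list passed camera at adjusted p = 1.89e-07, against adjusted p = 0.3996 with an estimated correlation. Other lists pointed up with few members called: T and NK cells (4 of 14, Nkg7 at 1.11, SE 0.22, adjusted p = 7.29e-05 by camera and adjusted p = 0.3796 with an estimated correlation), histone modifiers (7 of 30, Kmt2c at 0.45, SE 0.12, adjusted p = 0.00267 by camera and adjusted p = 0.3996 with an estimated correlation), interferon response (4 of 25, Usp18 at 0.74, SE 0.20, adjusted p = 0.000197 by camera and adjusted p = 0.574 with an estimated correlation) and B and plasma cells (1 of 8, adjusted p = 0.00324 by camera and adjusted p = 0.574 with an estimated correlation). Of these 4 lists 1, 0, 2 and 0 genes were called without the 7 libraries. The lymph node list (3 up and 1 down of 7, adjusted p = 0.0481 by camera and adjusted p = 0.574 with an estimated correlation) had 0 up and 1 down without them, and CORT_15w replicate 4 stands apart for B cell genes. Glucocorticoid targets held 4 rises and 5 drops of 30 and were not called (adjusted p = 0.404), with Per1 up (1.23, SE 0.32) and Mt2 (-2.33, SE 0.57) and Hsd11b1 (-1.53, SE 0.38) down.

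The lists not called in the difference were clock (3 up, 0 down, adjusted p = 0.1295), lipolysis (2 and 2, 0.366), thermogenic (1 and 0, 0.366), adipocyte (1 and 0, 0.9199), and insulin handling (3 and 2, 0.160000). They were also extracellular matrix (2 and 4, 0.366), macrophage (1 and 0, 0.05396), neutrophil and mast cell (2 and 0, 0.160000), inflammation (2 and 7, 0.9199), and preadipocyte (3 and 1, 0.242). The remaining ones were mesothelial (0 and 0, 0.366), smooth muscle (4 and 1, 0.124), skeletal muscle (0 and 0, 0.895), epididymis and testis (0 and 0, 0.9199) and ribosomal protein (0 and 0, 0.454). Median and mean differed in sign for inflammation (0.26 and -0.16) and adipocyte genes (both within 0.01 of 0), and the epididymis list had a median of -0.54 and a test pointing up. Adjusted over the list alone, members up and down were 0 and 16 for cholesterol synthesis, 1 and 10 for lipogenesis, 16 and 2 for endothelial, and 6 and 0 for T and NK cell. They were 0 and 14 for proliferation, 0 and 12 for oxidative phosphorylation, 0 and 9 for immediate early, 9 and 0 for histone modifiers, 0 and 7 for ER stress and 5 and 6 for glucocorticoid targets. They were 3 and 2 for lipolysis, 2 and 1 for thermogenic, 4 and 2 for insulin handling, 2 and 6 for extracellular matrix, 2 and 1 for neutrophil and mast cell and 4 and 8 for inflammation, and equal for the other lists. Camera called 15 lists with the preset correlation (19 without the 7 libraries), 0 with an estimated one (4 at an unadjusted p below 0.05), and fry called 8. The lists called only without the 7 libraries were extracellular matrix (adjusted p = 0.00402), neutrophil and mast cell (0.00912), smooth muscle (0.0167) and ribosomal protein (0.0224), the last with its direction turned to up. Quantile normalization also called ribosomal protein as up (0.000127), called lipolysis (0.0232) and insulin handling (0.00807), and ended triglyceride synthesis (0.319), fatty acid oxidation (0.189921), oxidative phosphorylation (0.232), lymph node (0.158) and ER stress (0.547). Fry ended triglyceride synthesis and immediate early (0.0519 each), oxidative phosphorylation (0.0624), B and plasma cells and ER stress (0.0773 each), interferon response (0.0995) and lymph node (0.1002, and 0.144 by total reads).

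Single libraries ended 2 list calls of the difference. The lymph node call was lost without CORT_5w replicates 1, 3 or 5, CORT_15w replicate 4, VEH_5w replicates 1, 2 or 3, or VEH_15w replicates 2 to 5 (adjusted p = 0.0523 to 0.102), range 0.0218 to 0.574 over its alternatives. The triglyceride call was lost without CORT_5w replicates 1 or 3, CORT_15w replicate 4, VEH_5w replicates 3 or 4, or VEH_15w replicates 2, 3 or 4 (0.0523 to 0.0958), range 0.00694 to 0.595. The macrophage list was called without CORT_5w replicates 1, 2 or 3, CORT_15w replicates 3 or 4, VEH_5w replicates 1 or 3, or VEH_15w replicate 2 (0.00274 to 0.0441), by voom (0.0445), on thinned reads (0.0391), by total reads (0.0165) and with a pseudocount of 0.1 (0.0464). Extracellular matrix was called without CORT_5w replicate 3 (0.0265) and smooth muscle without CORT_5w replicate 4 (0.00135). Among named genes, C7, Col6a5, Cycs, Hadhb, Hsd11b1, Kmt2c, Mt2, Pcna, Per1, Rgs1 and Tie1 were not called without the 7 libraries, with adjusted p from 0.0527 (Cycs) to 0.321 (Rgs1). All 11 kept their sign, 2 with a fold at least as large, and the median ratio of the folds was 0.792 and of the SE 1.197. Col6a5 was not called without CORT_5w replicate 2 or 5, CORT_15w replicate 3, VEH_5w replicate 3 or VEH_15w replicate 3 (0.0511 to 0.0611). Rnase2a was not called by voom (adjusted p = 0.111) or on thinned reads (0.110), Rgs1 not on thinned reads (0.0547), and Usp18 not after quantile normalization (0.0617).

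The comparison of VEH at 15 weeks with VEH at 5 weeks asked whether the control tissue changed with age. Ppp1r10, a regulator of nuclear protein phosphatase (log2 fold change 1.08, SE 0.17, adjusted p = 0.0465), and Ints6, a subunit of the integrator complex (log2 fold change 0.63, SE 0.10, adjusted p = 0.0465), rose, and 0 genes fell by limma. Both are named since the count is small, after their values were seen. At an unadjusted p below 0.05, 546 genes were higher and 419 lower. By voom, quantile normalization and scaling by total reads 0 genes were called, and with array weights 14 were higher and 1 lower. Leaving out VEH_15w replicate 5, high in Prm2 and Crisp1, gave 13 genes, and leaving out any of the 9 other VEH libraries gave 0. Simulated changes of log2 1 were recovered for 55.2% of genes in this contrast, so the low count does not show that the control groups were alike.

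H3K27ac, a mark of active promoters and enhancers, H3K4me3, a mark of promoters, and H3K27me3, a mark of repressed chromatin, were compared from the authors' deposited tables. At 5 weeks the authors called 6819 H3K27ac sites gained and 53 lost in CORT of 39581, 12065 H3K4me3 sites gained and 3 lost of 23236, and 1304 H3K27me3 sites gained and 0 lost of 7792. At 15 weeks they called 4377 H3K27ac sites gained and 0 lost of 28322, 14603 H3K4me3 sites gained and 0 lost of 31037, and 954 H3K27me3 sites gained and 0 lost of 5992. Among the gained H3K27ac sites were chromosome 1 146091690 to 146096554 at 5 weeks (log2 fold 2.01, FDR = 0.000161) and chromosome 8 47970276 to 47981387 at 15 weeks (1.87, FDR = 1.06e-08). Lost sites included chromosome 9 46021554 to 46026415 for H3K27ac (-0.92, FDR = 0.00448) and chromosome 8 3655445 to 3658211 for H3K4me3 (-0.93, FDR = 0.00929), both at 5 weeks. Positions are in mm9.

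The gains were spread over nearly all sites, gained or not. The fold was above 0 at 90.6% of H3K27ac, 97.8% of H3K4me3 and 93.3% of H3K27me3 sites at 5 weeks, with median log2 folds of 0.48, 0.61 and 0.56. At 15 weeks the shares were 91.7%, 94.7% and 96.0%, with medians of 0.71, 0.85 and 0.65. With each fold centred on the median of its table, a test added after seeing the data, 16 H3K27ac sites were gained and 231 lost, 0 H3K4me3 gained and 18 lost, and 0 H3K27me3 gained and 3 lost at 5 weeks. At 15 weeks these were 0 and 0, 6 and 36, and 0 and 2. Centring itself sets the balance of gained and lost sites. At an unadjusted p below 0.05 in the deposited tables, the marks with 0 lost sites had 0 lost H3K27me3 sites at 5 weeks and 5 H3K27ac, 1 H3K4me3 and 1 H3K27me3 at 15 weeks. The 15 week H3K27ac table names only the second CORT library, so whether its calls rest on 1 CORT library is open.

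**Figure D5:**
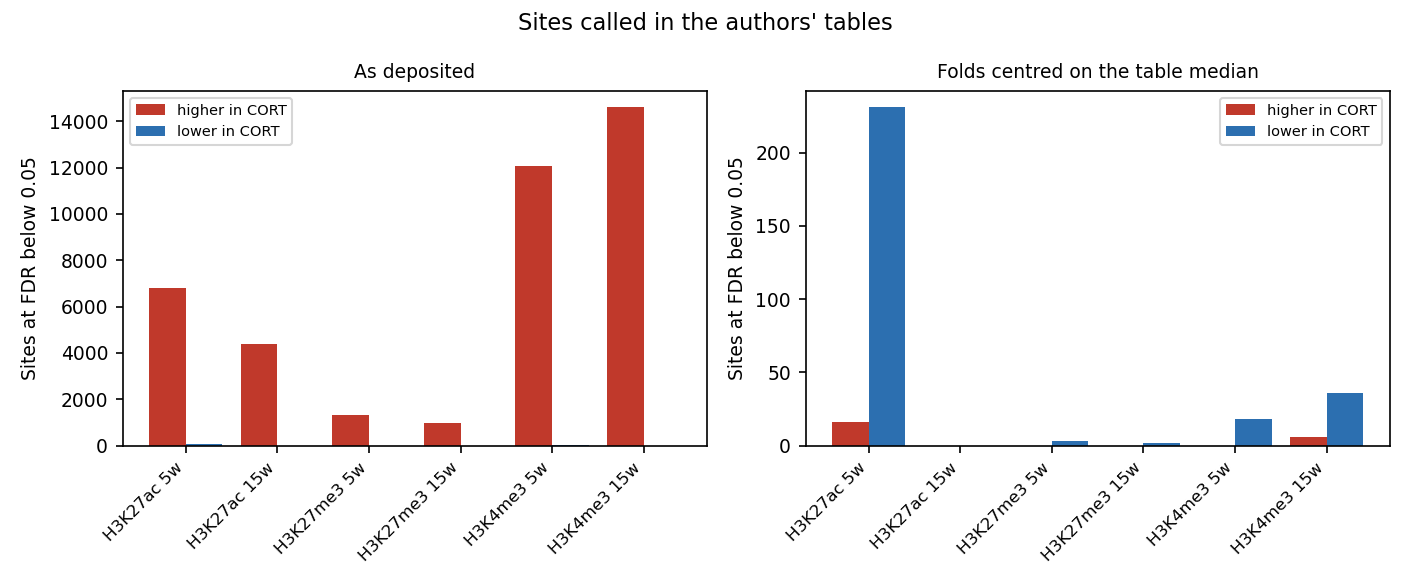
Number of sites gained and lost in CORT in the authors' deposited tables at an FDR below 0.05, for 3 marks and 2 times, as deposited and after centring each fold on the median of its table. As deposited, gained sites number 954 to 14603 and lost sites 0 to 53.

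Sites gained at 5 weeks were often gained at 15 weeks. Among sites tested at both times, 2224 H3K27ac sites were gained at both against 921 by independent lists (odds ratio 6.15, Pearson r of the folds 0.746, with that limit of the 15 week table), 11327 H3K4me3 sites against 7932 (odds ratio 34.5, r = 0.286), and 578 H3K27me3 sites against 260 (odds ratio 6.35, r = 0.289). Sites are not independent replicates. Marks were compared at sites that overlap. At 5 weeks 2204 sites gained H3K27ac and H3K4me3 against 2219 by independent lists (odds ratio 0.971, Fisher's exact test p = 0.507), while the folds correlated at r = 0.450, and at 15 weeks 2054 against 1954 (odds ratio 1.35, Fisher's exact test p = 7.02e-08, r = 0.357). For H3K27me3 with H3K4me3 they were 303 against 314 at 5 weeks (Fisher's exact test p = 0.407, r = -0.0304) and 389 against 403 at 15 weeks (Fisher's exact test p = 0.216, r = -0.0845). For H3K27me3 with H3K27ac they were 21 against 37.4 at 5 weeks (Fisher's exact test p = 0.000640, r = -0.323) and 1 against 3.99 at 15 weeks (Fisher's exact test p = 0.150, r = -0.372).

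The peak lists differed as much within groups as between them. Libraries had 1810 to 52108 peaks of H3K27ac, 18124 to 38728 of H3K4me3 and 2255 to 11090 of H3K27me3. H3K27ac of CORT at 15 weeks had 1810 and 29341, a ratio of 16.2. The median share of a library's peaks that overlapped the other library of its group was 69.7% (H3K27ac 69.7%, H3K4me3 76.9%, H3K27me3 57.7%). The Jaccard index in bp was 0.351 within groups and 0.437 between CORT and VEH of the same time for H3K27ac, 0.612 and 0.620 for H3K4me3, and 0.283 and 0.343 for H3K27me3. With 2 libraries per group no test of peak numbers was made. In 11 input tables, 8.07% (H3K27ac, VEH at 15 weeks) to 92.0% (H3K27ac, VEH at 5 weeks) of sites lay above input (FDR below 0.05). Median log2 folds were 1.62 to 2.86. Where both groups had tables, only H3K27me3 at 15 weeks had a higher share in CORT.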

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

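The tests of testis, epididymis and liver RNA, of centred folds, of more mark in the tissue, of the clock members, of the time of sampling, of adipocyte number and of thinned reads were chosen after seeing the data.

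Transcripts of other tissues lay far from the rest of their group in 12 of 28 checks of marker genes (4 groups each). The gap to the nearest library exceeded 0.71 of the range of the group's 5 libraries for Alb in CORT_5w replicate 2 (2095 FPKM), Prm2 in CORT_5w replicate 3 (184) and VEH_15w replicate 5 (570.4). It did so for Crisp1 in CORT_5w replicate 4 (1429.6), VEH_5w replicate 3 (649) and VEH_15w replicate 5 (1261). Akr1b7 stood out in CORT_5w replicate 4 (3947), VEH_5w replicate 3 (2115), CORT_15w replicate 4 (14.8) and VEH_15w replicate 5 (3.01), and Igj in VEH_5w replicate 4 (2.18) and Cd79b in CORT_15w replicate 4 (12.8). The same held for 15 of 334 checks of named genes by group, 4.49% where chance gives about 1 in 20 (5%). These were Tsc22d3 in VEH_5w replicate 2 (36.4 FPKM), Nr3c1 in CORT_5w replicate 2 (45.1), Chac1 in CORT_5w replicate 5 (10.3), and Itgax and Grb14 in VEH_15w replicate 1 (2.60 and 5.46). The others were Fcrls, H2-Eb1 and Cd74 in VEH_15w replicate 2 (3.63, 71.3 and 209.5), Timp1 and Chil3 in CORT_15w replicate 4 (9.67 and 2.27), Il1rn in VEH_5w replicate 2 (0.306), Mt2 in VEH_15w replicate 5 (111), Per1 in CORT_15w replicate 3 (29.6), Crtac1 in CORT_5w replicate 2 (10.2) and Ephb2 in VEH_5w replicate 5 (0.676). Of 8 checks of library measures 0 passed the limit.

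For the testis, epididymis or liver transcripts of 7 libraries, a library of another tissue under an adipose label is excluded, since Adipoq, Fabp4 and Plin1 stood at 0.498 to 1.37 times their group's median in all 7. Testis RNA is a candidate source in 4 libraries, where other abundant spermatid transcripts lay at a median of 58.6 to 185 times the others. Liver RNA is one in CORT_5w replicate 2, where other liver transcripts lay at a median of 153 times. In most libraries 11 of 30 liver, 2 of 20 spermatid and 1 of 23 epididymis genes reached 1 FPKM. Epididymis RNA stays open in 3 libraries, since other epididymis transcripts (median of 1 to 6.87 times) lay too near 0 to decide. The epididymis marker Spink8 stood at 217 to 499 FPKM there and up to 1.18 elsewhere. No biological explanation was tested, since the design has no group for it.

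Gains far outnumbered losses for all 3 marks at both times, and 1 scaling factor per library, a difference in background, and more mark in the tissue were weighed. With folds centred, the gained share of the calls was 0% to 14.3%, which leaves the factor open, since centring itself sets the balance. The absolute rank correlation of fold with level, which a difference in background would raise in every table, ran from 0.00801 to 0.623, so it is open at least for H3K4me3 at 15 weeks. Both CORT libraries had more peaks than both VEH libraries in 1 of 6 mark and time pairs, and in 0 pairs fewer, so more mark in the tissue stays open too. These explanations cannot be told apart, since whether the spike-in scaled the values is not stated in the sources used here.

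Glucocorticoid targets lay lower in CORT at 5 weeks, with 15 of 30 lower and 5 higher. The 2 members shared with the clock list do not account for it, since 14 of the 15 lower genes are not on that list, and neither does the deeper sequencing of the CORT libraries, since 15 members were called lower with reads thinned to the smallest library. A shift of the time of sampling stays open, as Dbp changed by 0.61 and Arntl by -0.61 while Per1 and Nr1d1 went the other way from Dbp (-1.57 and -0.57). Fewer adipocytes stay open, as the adipocyte list had a median of 0.0932 with an interquartile range of 0.867. A response of the tissue to long exposure, which the design holds in its CORT groups, was not tested and stays open.

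Effects differed between 5 and 15 weeks, by the test of the difference itself (adjusted p below 0.05), for 61 of 114 named genes, a share raised by the naming rule, which picks genes by this contrast (16.7% of all genes). Falls at 5 weeks were smaller at 15 weeks, as log2 differences, for Cfd (3.25), Inmt (2.66), Cish (2.53), Fam13a (2.04), Mycl (1.74), Acsm3 (1.53), Zim1 (1.41), Per1 (1.23), Klf9 (0.72), Elane (0.78), Adrb3 (1.93), Kcnj8 (1.15) and Abcc9 (1.39). The same held for H2-Eb1 (1.95), Cd74 (1.68), Cd2 (1.05), Nkg7 (1.11), Ccr2 (1.65), Ccl11 (1.18), Usp18 (0.74), Tek (1.14), Tie1 (1.30), Pecam1 (0.88) and Kmt2c (0.45). The difference was also above 0 for Hcar1 (1.98), Penk (2.27), C7 (2.07), Fcrls (2.07) and Col6a5 (2.04). It was below 0 for the lipid genes Lss (-1.13), Nsdhl (-1.30), Mvk (-0.81), Acly (-1.87), Acss2 (-2.09), Dgat2 (-1.71), Agpat2 (-1.62) and Fabp5 (-2.38), for Acadm (-0.90), Hadhb (-0.92), Cycs (-1.53), Sdhc (-0.58) and Slc25a25 (-1.74). Further values below 0 were those of Timp1 (-3.15), Sparc (-1.04), Chil3 (-3.13), Rnase2a (-3.11), Il1rn (-2.81), Rgs1 (-2.56) and Ccl2 (-2.44), of Ccne1 (-1.19), Mcm5 (-1.14) and Pcna (-1.03), of Hspb7 (-2.46), Hspb1 (-2.03), Egr2 (-1.25), Ddit3 (-0.89) and Calr (-0.75), and of Mt2 (-2.33), Hsd11b1 (-1.53), Slc5a7 (-1.90) and Fgf13 (-1.38).

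The difference between times was called for 15 lists by camera at the preset correlation, and for 0 at the estimated one (adjusted p = 0.0782 to 0.595): cholesterol synthesis (adjusted p = 5.59e-10), endothelial (1.89e-07), antigen presentation (1.89e-07), oxidative phosphorylation (4.52e-06), proliferation (6.56e-06), lipogenesis (4.26e-05), and T and NK cell (7.29e-05). The others were interferon response (0.000197), fatty acid oxidation (0.000497), immediate early (0.000993), histone modifiers (0.00267), B and plasma cell (0.00324), ER stress (0.0127), triglyceride synthesis (0.0356) and lymph node (0.0481).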

How the results depend on the processing

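Limma voom, thinned reads, scaling by total reads, leaving out the 7 libraries with transcripts of other tissues, a block with 1 number over both times and centred site folds were tests chosen after seeing the data, and the other alternatives were chosen before. The cause of a change was not tested, except where the construction gives it (fewer genes, fewer libraries, a stricter threshold). No list or named gene that was called turned its direction, and 1 list that was not called did: ribosomal protein in the difference pointed down, and it was called as up with quantile normalization (adjusted p = 0.000127) and without the 7 libraries (0.0224). Counts stayed within 1.5 times, between 2434 and 4028 for rises at 5 weeks (13 of 14 alternatives other than single libraries), 2839 and 3743 for falls (11 of 14), 480 and 744 for rises at 15 weeks (8 of 14), 876 and 1285 for falls (9 of 14), 830 and 1286 for higher (7 of 12) and 1370 and 2133 for lower effects (7 of 12), and 887 and 1353 for genes called at both times in the same direction (10 of 14). Of 73 calls of named genes at 5 weeks 59 held in all alternatives and 14 ended only at a log2 fold change of at least 1, of 46 at 15 weeks 13, and of 36 differences 22.

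The other values were these. With no filter, 0 genes were higher in VEH with age. With a mean FPKM of at least 5, which tests fewer genes, 2115 fell at 5 weeks and 623 had a higher effect. Quantile normalization gave 1041 lower effects, 0 age genes and 1 list at 15 weeks. Fits of only the 2 groups compared gave 340 rises and 568 falls at 15 weeks, 0 age genes and 610 shared calls. The block on replicate number gave 213 and 480 at 15 weeks, 404 higher and 652 lower effects and 514 shared calls, and the block with 1 number gave 1 age gene. The block also ended the 5 week calls of fatty acid oxidation and ER stress (adjusted p = 0.0532 each) and the differences of Cish, Col6a5, Hsd11b1, Kmt2c, Pcna and Rgs1 (0.0531 to 0.0927), and called the macrophage list in the difference (0.0325). Array weights gave 14 genes higher and 1 lower with age. A log2 fold change of at least 1, a stricter threshold, gave 627 and 380 at 5 weeks, 76 and 76 at 15 weeks, 223 and 247 for the difference, 1 with age and 116 shared calls. The authors' deposited table gave 985 rises at 15 weeks. The estimated correlation gave 0, 0 and 0 lists at 5 weeks, at 15 weeks and for the difference, and fry gave 0 at 15 weeks and 8 for the difference. Voom gave 0 age genes on all and on thinned reads. Scaling by total reads gave 1083 rises and 626 falls at 15 weeks, 1782 higher and 938 lower effects and 0 age genes. Without the 7 libraries, 1963 genes fell at 5 weeks, 55 rose and 94 fell at 15 weeks, 214 effects were higher and 502 lower, 1 gene was higher with age, 123 calls were shared and 14 lists were called at 15 weeks.

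For sites, an FDR below 0.01 left 1305 of the H3K27ac calls at 5 weeks and 1520 at 15 weeks, and of H3K27me3 524 and 125. A log2 fold of at least 1 left 2293 of H3K27ac, 193 and 163 of H3K27me3 and 523 of H3K4me3 at 5 weeks. Centring gave 247 and 0 calls of H3K27ac, 3 and 2 of H3K27me3 and 18 and 42 of H3K4me3 at 5 and 15 weeks, most of them lost sites not called before. The stricter choice of peaks keeps a fixed share of each library's peaks by construction, so its median of 10407 peaks per library tests nothing. A reciprocal overlap of 0.5 gave a replicate overlap of 44.8%.

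Leaving out single libraries gave 3034 to 3571 rises and 2896 to 3333 falls at 5 weeks, 260 to 727 and 438 to 1293 at 15 weeks, 652 to 1333 higher and 1082 to 1929 lower effects, 0 to 13 genes higher and 0 lower with age, 538 to 1333 shared calls, and 14 to 17, 4 to 8 and 13 to 16 lists at 5 weeks, at 15 weeks and for the difference.

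The 3 intended comparisons of RNA with marks, with their 9 alternatives each, were not run, since no mm9 gene annotation was used. Replicate numbers do not pair the RNA libraries: within a time, CORT and VEH of the same number correlated above 0.1 in 4 of 10 pairs after removing group means (from -0.48 to 0.36). The authors' site tests could not be paired, and the peak lists were not paired. A simulated log2 change of 0.5 in few genes was recovered for 25.4% at 5 weeks, 28.4% at 15 and 7.69% in the difference.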

Other observations

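Pericyte genes went both ways at 5 weeks, picked after the values were seen. The potassium channel subunits Kcnj8 (-1.62, SE 0.19) and Abcc9 (-1.52, SE 0.24) fell and the proteoglycan Cspg4 rose (1.39, SE 0.23), on a list that was not called (3 up, 4 down of 13). The adrenergic receptor Adrb3 fell (-1.61, SE 0.22).

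The splits with 5 week calls or treatment kept were chosen after seeing the data.

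Other splits of the same libraries show which counts chance can give, with 100 per count, the real one included. Chance is unlikely for the 6835 genes of 5 weeks (at most 2267 in other splits, 1 of 100 as large). For the 1659 of 15 weeks (at most 1351, 1 of 100), a near split leaves library structure open. For the 2600 genes called in the difference (at most 1, 1 of 100) and the 1076 called at both times in the same direction (at most 0, 1 of 100), splits of CORT against VEH at both times decide nothing, since they also remove the calls of each time. With the 5 week calls kept and the 15 week libraries split, no other reached the 1076 (at most 781, 1 of 100). Splits of the times within CORT and within VEH, with treatment kept (at most 1, 1 of 100), decide nothing for the 2600 either. Such splits add the difference itself to the spread between libraries. For the 2 genes called with age in VEH, 4 of 100 splits gave as many, and 1 of these other splits gave 237, several times the real count, which points to a structure of the samples whose source was not tested. Chance cannot be excluded for the number of lists: 8 of 100 splits gave the 17 lists of 5 weeks or more (at most 19), 95 gave the 6 of 15 weeks or more (at most 21), and 21 gave the 15 of the difference or more (at most 18), as did 18 with treatment kept (at most 19). These splits do not separate a structure of the libraries from correlation between list members, estimated at 0.0561 to 0.915 against the preset 0.01. Chance cannot be excluded for the 72.8% of genes called at 5 weeks that kept their sign at 15 weeks, as 16 of 100 splits gave as high a share (at most 81.1%).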
